A study of Homo sapiens with 12 samples.

How the data were processed

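Bulk RNA sequencing was carried out on human embryonic stem cells of the UCLA1 line and on incipient mesoderm-like cells (iMeLC), the short-lived intermediate through which stem cells pass before they are turned into primordial germ cell-like cells. Lines with the catalytic domain of TET1 knocked out (CDKO) were compared with control lines (CTRL). TET1 is an enzyme that oxidises 5-methylcytosine in DNA. There were 3 libraries in each of the 4 groups, CTRL hESC, CDKO hESC, CTRL iMeLC and CDKO iMeLC, 12 libraries in all. Per the labels' protocols, total RNA was extracted from sorted cells or cell pellets with the RNeasy micro kit, and libraries were made with the SMARTer Stranded Total RNA kit. Whether ribosomal RNA was depleted is not given in the sources used here.

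The deposited values were whole-number read counts per gene symbol, not normalised, in one table for the hESC libraries and a separate table for the iMeLC libraries. Per the submitters' processing notes, FastQC, cutadapt, edgeR and the GRCh38 build were used. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies therefore cannot be assigned with certainty, and counts of named genes of that kind are uncertain wherever they are given. Exons overlapped those of an annotated gene on the opposite strand for B4GALNT1, CCND1, CDH2, CGAS, CHP2, COLEC12, ENO1, FDFT1, GAD1, GATA6, GRIN1, HIST2H3PS2, HOXA7, IER2, LEF1, MAGEA4, MEIOC, NKX1-2, NNAT, NODAL, PCDHB15, PDE3A, PHLDA1, POU3F4, RBM46, SALL2, SCNN1G, SEC14L4, SLC2A1, SLITRK1, SPARC, TM4SF1, TP53I3, TSPEAR-AS1, TYMS, VIM, WLS and AL627171.2. They overlapped on the same strand for CCDC125, COL3A1, HIST2H3PS2, L1TD1, MEIOC, MMP2, MT-ND4, MT1B, MTRNR2L13, PCDHB15, PCDHGC4, SLC2A1 and TRIM4. The MTRNR2L genes, the metallothioneins MT1B and MT1H, the histone HIST2H3PS2, the MAGEA family member MAGEA4 and the protocadherins have close copies, and annotated pseudogenes carry the names of ACTB, AKR1B10, CD24, CEND1, COX6C, ENO1, HTR1D, LDHA, PCNA, SALL4, TERF1, TET1 and TYMS. Each table held 36762 gene symbols, of which 34217 (93.1%) matched exactly 1 gene of GENCODE release 29. That annotation, on GRCh38, was used for gene coordinates, gene types and overlaps. Library totals ranged from 12517593 to 18855099 counts in hESC and from 52121702 to 109479071 counts in iMeLC, so low counts were measured with less counting error in iMeLC.

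The iMeLC columns carry the number of the line. The hESC columns name the genotype and a replicate from 1 to 3 but no line, so each was assigned to its group and to no particular line. Stage coincided with the table, with the date each table carries and with depth, so a stage difference cannot be told apart from a difference between the tables. Replicate libraries of a group were compared by a chi-square test of their counts, which gave between 4.41 and 198 per gene where sampling noise alone gives about 1, and no pair was treated as a single library deposited more than once. The labels name separate lines in each group and do not say when the cultures were grown. P-values therefore measure the spread between libraries, in which line, culture and library preparation cannot be told apart. The labels place the same lines in both stages. The fits over both stages treat all 12 libraries as independent, so their p-values do not take account of this pairing.

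Differential expression was tested with edgeR 4.0.16 under R 4.3.3, by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) after TMM normalisation and filterByExpr, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The CDKO against CTRL comparisons were fitted within each stage on 6 libraries. The iMeLC against hESC comparisons in each genotype and the genotype by stage interaction, which asks whether the genotype difference itself differed between the stages, were fitted over all 12 libraries with 4 group means. A table difference common to both genotypes cancels in the interaction. CPM, a gene's count scaled to a common library total, were computed with TMM-scaled library sizes within the fit, so a gene's CPM in a stage comparison differs slightly from its CPM in a genotype comparison, and log2 fold changes are those of the fit, with standard errors derived from the test. TET1 was also compared by an exact two-sided permutation test on log2 CPM, which with 3 libraries against 3 cannot go below 0.1.

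The design, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. For each comparison the rule named TET1, TET2 and TET3, the 10 genes with the largest rise and the 10 with the largest fall among called genes of at least 1 CPM whose libraries did not overlap between groups (clone-based symbols left out), and up to 4 members of each gene list described, those with the smallest adjusted p or, in a list with no call, the highest mean CPM. The interaction had no rule on overlap, and since fewer than 5 genes passed there, the 5 genes with the smallest p were named. Genes chosen after their values were seen are marked so. For genes with 1 to 3 counts in a group the ratio of pooled counts is given with its exact conditional 95% interval. For a group at 0 the ratio is a lower bound against a floor of 3 counts over the group. PCR duplicates are not independent molecules, so these intervals cover counting error only.

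There were 33 gene lists: TET enzymes and base excision partners, DNA methylation writers and maintenance, core pluripotency, naive pluripotency, primed pluripotency, primitive streak and mesendoderm, definitive endoderm, primordial germ cell, amnion and trophectoderm, neuroectoderm, neural crest, later mesoderm, germline and meiosis, imprinted genes, HOX clusters, the protocadherin beta cluster, WNT targets, NODAL and activin targets, BMP targets, FGF and ERK targets, p53 targets, integrated stress response, hypoxia and glycolysis, cholesterol synthesis, epithelial genes, mesenchymal transition, fibroblast or feeder cell markers, mitotic genes, DNA replication, dissociation and immediate early genes, replication-dependent histones, mitochondrially encoded genes and neighbours of 20q11.21, a site of frequent copy number gain in stem cell cultures. Each list was tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated from the libraries, and fry tested whether a list moved in 1 direction on balance without reference to other genes. Member genes were also counted with p adjusted over the list alone.

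Each comparison was tested on simulated data, with counts drawn from the means, dispersions and library sizes of the real libraries and a set of genes changed by known amounts. At a 2-fold change the test recovered 70.3% of changed genes for CDKO against CTRL in hESC (16896 genes tested), 41.5% in iMeLC (19511 genes), 43.8% for the stage comparison in CTRL (19395 genes), 48.5% in CDKO (19397 genes) and 24.6% for the interaction (19423 genes). At a 4-fold change the shares were 98.5%, 72.7%, 73%, 75.4% and 57.8%, in the same order.

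Alternatives were the median-of-ratios and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, removal of the 13 mitochondrially encoded genes and 4 ribosomal or small RNA genes, a fit over 12 or 6 libraries, and leaving out single libraries. Leaving out both libraries of a line and treating the line as a block had been planned and could not be run, because the hESC columns name no line. Leaving out single libraries in the fits over both stages, for the correlation of genotype effects and for the list tests, removal of AL627171.2, a gene whose span holds the signal recognition particle RNA gene RN7SL2, and the other scaling factors for the list tests were chosen after seeing the data. No library or gene beyond the expression filter was left out of the reported fits. Results for some named genes are not reported here. Levels of genes that could show the sex of a sample are not reported here.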

Results

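The series asked how TET1 catalytic activity bears on human germ cell fate, and these libraries profiled gene expression in the stem cells and in the iMeLC stage on the way to germ cell-like cells. Each of the 4 groups held 3 libraries. Library totals were 16325691, 17804540 and 18855099 counts in CTRL hESC 1 to 3 and 12517593, 18556180 and 16958407 counts in CDKO hESC 1 to 3. In iMeLC, whose libraries are named by line, the totals were 97345795 (CTRL1101), 91226186 (CTRL1106), 109479071 (CTRL1109), 52121702 (CDKO1102), 89723454 (CDKO1105) and 79568371 (CDKO1312) counts. Between 24733 and 28754 genes had a count in the hESC libraries and between 23779 and 26020 in the iMeLC libraries. Mitochondrially encoded genes took 2.5% (CTRL1101 iMeLC) to 4.04% (CTRL1109 iMeLC) of counts. The most counted gene was ACTB in every hESC library, at 1.038% to 1.342%. In every iMeLC library it was AL627171.2, a non-coding gene whose span holds RN7SL2, at 1.209% to 1.787% in CTRL and 0.772% to 0.995% in CDKO.

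TET1 (ENSG00000138336, GRCh38 chromosome 10, 68560656 to 68694482, plus strand) was counted at similar levels in both genotypes. In hESC it stood at 325, 379.9 and 344 CPM in the CTRL libraries and 424, 448 and 378 CPM in the CDKO libraries, a log2 fold change of 0.25 (SE 0.09, adjusted p = 0.209, exact permutation p = 0.2). In iMeLC it stood at 257, 289 and 265 CPM in CTRL and 288, 309 and 268 CPM in CDKO, a log2 fold change of 0.09 (SE 0.09, adjusted p = 0.577, exact permutation p = 0.3). With 3 libraries against 3 the smallest two-sided exact p is 0.1, over 20 permutations. Counts were summed over the whole gene and do not separate the exons of the catalytic domain, so this total can neither show nor exclude its loss. The other TET dioxygenases did not pass either, with log2 fold changes in hESC of 0.29 for TET2 (adjusted p = 0.201) and 0.18 for TET3 (adjusted p = 0.313), and in iMeLC of 0.43 for TET2 (adjusted p = 0.329) and 0.14 for TET3 (adjusted p = 0.47).

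In hESC, 103 genes were higher and 123 lower in CDKO than in CTRL, of 17222 tested. These comparisons ask what loss of the catalytic domain changed before and after the first step of differentiation. The deepest fall was of TSPYL5, a nucleosome assembly protein family member on chromosome 8 (97273474 to 97277964), from 19.3 ± 5.7 CPM (SD, n = 3) to 0.496 ± 0.383 CPM. ANKRD35, an ankyrin repeat gene, fell from 18.6 ± 3.82 to 2.16 ± 0.691 CPM. HOXA7, a HOX transcription factor of body axis patterning, rose from 0.132 ± 0.034 to 2.22 ± 0.833 CPM, and the homeobox gene HMX1 rose from 0.651 ± 0.138 to 3.97 ± 0.284 CPM. NODAL, the ligand that keeps stem cells primed and induces mesendoderm, rose from 28.4 ± 9.31 to 71.6 ± 21.7 CPM.

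The log2 fold changes were -5.24 for TSPYL5 (SE 0.42, adjusted p = 0.00149), -3.13 for ANKRD35 (SE 0.24, adjusted p = 0.00144), 4.01 for HOXA7 (SE 0.47, adjusted p = 0.0125), 2.59 for HMX1 (SE 0.27, adjusted p = 0.00945) and 1.34 for NODAL (SE 0.25, adjusted p = 0.0374). HOXA7 lies opposite HOXA-AS3 and its count is uncertain without the strand setting. The other genes with the largest rises were C1QL4 (log2 fold change 2.85), NLRP10 (2.54), the Nogo receptor relative RTN4RL1 (2.52), the sodium channel subunit SCNN1B (2.44), AADACL3 (2.32), LUZP2 (2.16), the homeobox gene IRX4 (2.16) and SLITRK1 (2.06), with adjusted p from 0.0146 (NLRP10) to 0.0418 (IRX4). The other large falls were of the zinc finger gene ZNF560 (-5.13), SEC14L4 (-3.99), FRMD1 (-3.31), the axonal adhesion gene CNTN2 (-2.89), CDC42EP5 (-2.82), CCDC125 (-2.81), PHYHIP (-2.75) and the synaptotagmin SYT5 (-2.68), with adjusted p from 0.00572 (SEC14L4) to 0.0496 (SYT5). ZNF560 stood at 30.9, 1.70 and 31.3 CPM in CTRL hESC 1 to 3, and in iMeLC at 30.6, 0.801 and 28.3 CPM in CTRL1101, CTRL1106 and CTRL1109, so CTRL1106 lay below CDKO1312 (2.36 CPM).

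Among gene lists, NODAL and activin targets were higher in CDKO hESC (camera adjusted p = 1.73e-04, adjusted p = 0.741 with an estimated correlation). Of 13 members tested 13 had a positive fold change, 1 was called (NODAL) and 9 were called higher when adjusted over the list alone. Primitive streak and mesendoderm genes were higher (camera adjusted p = 1.82e-04, adjusted p = 0.741 with an estimated correlation), with 2 of 15 called higher and 7 adjusted over the list alone. The called members were NODAL and NKX1-2, a posterior homeobox gene that rose from 49.9 ± 3.24 to 77.8 ± 5.71 CPM (log2 fold change 0.64, adjusted p = 0.0146). HOX genes were higher (camera adjusted p = 6.59e-04, adjusted p = 0.509 with an estimated correlation, fry adjusted p = 0.00555). No other list passed fry in this comparison. Only 3 of 39 passed the expression filter, of which HOXA7 was called and 2 passed adjusted over the list alone. The mean log2 CPM of these 3 was -0.87, -1.26 and -1.1 in CTRL hESC 1 to 3 and 0.57, 0.52 and 0.55 in CDKO hESC 1 to 3. HOX genes low in both groups could not enter, which favours genes high in 1 group, so the result does not speak for the HOX genes as a whole. Core pluripotency genes were higher (camera adjusted p = 0.00777, adjusted p = 0.741 with an estimated correlation), with 1 of 19 called (NODAL), 8 adjusted over the list alone and a median log2 fold change of 0.157.

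Naive pluripotency genes passed with 1 of 13 called, NLRP7 (1.25, adjusted p = 0.0349), and 2 adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.741 with an estimated correlation). FGF and ERK targets passed with 1 of 16 called, the feedback inhibitor SPRY2 (0.49, adjusted p = 0.019), and 2 adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.741 with an estimated correlation). Hypoxia and glycolysis genes were lower, with 1 of 17 called, the vasodilator peptide gene ADM (-1.01, adjusted p = 0.0167), and 2 adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.741 with an estimated correlation). The integrated stress response list was higher with 0 of 15 called and 1 adjusted over the list alone (camera adjusted p = 0.0217, adjusted p = 0.79 with an estimated correlation). Later mesoderm genes were higher with 0 of 9 called, and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0357, adjusted p = 0.741 with an estimated correlation).

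The library CDKO hESC 3 stood apart in mesendoderm and endoderm genes. It held 61.9 CPM of SOX17, 44.9 CPM of GATA6 and 41.2 CPM of EOMES, against 4.98 and 5.12, 2.04 and 4.19, and 5.55 and 8.59 CPM in the other CDKO hESC libraries. CTRL hESC 1 held 9.54, 7.88 and 10.6 CPM of them, more than CDKO hESC 1 and 2, and its mean log2 CPM over the primitive streak list, 3.43, was above that of CDKO hESC 1 (3.00). These genes were picked after their values were seen. Without that library the adjusted p was 0.00641 for NODAL and activin targets, 0.0105 for the primitive streak list and 4.62e-05 for HOX genes. Over all single-library omissions these ranged from 2.13e-06 to 0.00641, 2.13e-06 to 0.0138 and 4.62e-05 to 0.00282, and core pluripotency from 0.00214 to 0.0497. The other 5 lists lost their call in at least 1 omission. The integrated stress response reached 0.0898 without CTRL hESC 3 and 0.0612 without CDKO hESC 3 (range from 0.00214), and FGF and ERK targets 0.108 without CTRL hESC 3 and 0.0602 without CDKO hESC 1 (range from 0.00397). Naive pluripotency reached 0.0534 without CDKO hESC 1 (range from 0.00618), and hypoxia and glycolysis 0.462 without CTRL hESC 2 and 0.0825 without CDKO hESC 2 (range from 0.00671). Later mesoderm reached 0.0652, 0.144, 0.0534 and 0.0794 without CTRL hESC 2, CTRL hESC 3, CDKO hESC 1 and CDKO hESC 2 (range from 0.0109).

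Lists that camera called in no comparison were TET enzymes and base excision partners (camera adjusted p = 0.598 in hESC and 0.621 in iMeLC), DNA methylation writers (0.598 and 0.962), primordial germ cell genes (0.102 and 0.193), neuroectoderm (0.598 and 0.509), neural crest (0.924 and 0.0993), imprinted genes (0.598 and 0.678), epithelial genes (0.924 and 0.509), mitotic genes (0.246 and 0.818), replication-dependent histones (0.353 and 0.678) and neighbours of 20q11.21 (0.246 and 0.193). Their lowest camera adjusted p in the other comparisons was 0.0616. Fry passed for none of them in the genotype comparisons or the interaction, but in the stage comparisons in CTRL and CDKO it passed for mitotic genes (adjusted p = 4.95e-05 and 1.25e-05), 20q11.21 neighbours (3.01e-04 and 0.00128), DNA methylation writers (0.0101 and 0.00297), neural crest (0.0101 and 0.038) and imprinted genes (0.0105 and 4.1e-04). It also passed in CTRL for neuroectoderm (0.0194, with 0.136 in CDKO) and in CDKO for primordial germ cell genes (0.0363), epithelial genes (0.0363) and histones (0.0317), with 0.177, 0.0614 and 0.207 in CTRL. Single members were called nonetheless. The imprinted genes NNAT, a membrane proteolipid gene opposite BLCAP and so uncertain, and NAP1L5 fell in hESC (-1.75, adjusted p = 0.016, and -2.39, adjusted p = 0.0193), while GRB10, a growth factor receptor adaptor, rose (0.56, adjusted p = 0.0321). The claudin CLDN4 fell (-1.29, adjusted p = 0.0169), and so did FDFT1 of cholesterol synthesis (-0.42, adjusted p = 0.0476), whose list had an adjusted p of 0.246. The imprinted list had a median of 0.027 and a mean of -0.06 in hESC, and 0.233 and -0.14 in iMeLC, with an upward camera direction both times.

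Of the 226 genes called in hESC by edgeR, 225 had no overlap between the groups' libraries. With 3 libraries against 3 a call nearly requires this, so it is no separate support for the calls. Over all tested genes 22.1% had none, where chance gives 10%. The number of calls depended on single libraries, with 102 genes without CTRL hESC 1, 493 without CTRL hESC 2, 28 without CDKO hESC 1, 5 without CDKO hESC 2 and 41 without CDKO hESC 3. The share of lower genes, 54.4%, was 43.6% without CTRL hESC 2, 41.5% without CDKO hESC 3 and 68.1% in the fit over 12 libraries. Log2 fold changes moved by more than 1.5 times on the linear scale for SCNN1B (3.31), AADACL3 (3.12) and IRX4 (3.04) without CTRL hESC 2, and TSPYL5 (-6.09) and PHYHIP (-3.68) without CDKO hESC 2. The same held for FRMD1 without CDKO hESC 1, which left 3 counts in CDKO and a ratio of 26.6 (8.9 to 131). Of the 20 genes named for their change, TSPYL5 (adjusted p up to 0.017) and ANKRD35 (up to 0.0319) stayed called in all 6 omissions, and 18 were lost in at least 1, with SYT5 reaching 0.238 without CDKO hESC 2. HOXA7 and HMX1 were lost without CDKO hESC 2 alone (adjusted p = 0.0577 for both). Of the list members, NODAL, SPRY2 and CLDN4 were lost without CTRL hESC 1 or any 1 CDKO library, NLRP7 also without CTRL hESC 3, NKX1-2 and GRB10 without any 1 CDKO library, NAP1L5 without CTRL hESC 1, CDKO hESC 2 or CDKO hESC 3, ADM without CDKO hESC 2 or CDKO hESC 3, NNAT without CDKO hESC 2, and FDFT1 in each of the 6 omissions. The highest adjusted p, without CDKO hESC 2, was 0.145 for NODAL (range over alternatives from 0.00847), 0.0885 for NKX1-2 (from 1.8e-06), 0.143 for NLRP7 (from 3.51e-04), 0.115 for SPRY2 (from 2.56e-04) and 0.11 for ADM (from 2.75e-08). It was also 0.11 for NNAT (from 5.31e-10), 0.103 for NAP1L5 (from 5.14e-07) and 0.107 for CLDN4 (from 3.85e-05). For GRB10 it was 0.153 (from 9.56e-05) and for FDFT1 0.175 (from 0.00259), both without CDKO hESC 1.

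In iMeLC, 16 genes were higher and 53 lower in CDKO, of 19999 tested. TRIM4, a ubiquitin ligase gene on chromosome 7 (99876958 to 99919600), rose from 0.0326 ± 0.0107 CPM (SD, n = 3) to 6.77 ± 0.789 CPM. TRDN, which encodes triadin of the muscle sarcoplasmic reticulum, rose from 8.37 ± 1.82 to 46.3 ± 3.97 CPM. TSPYL5 fell from 10.3 ± 5.32 to 0.0476 ± 0.0459 CPM, the cytosolic DNA sensor gene CGAS from 9.33 ± 1.56 to 0.14 ± 0.107 CPM, and the interferon-induced GTPase gene MX2 from 2.9 ± 0.602 to 0.0274 ± 0.0299 CPM. The germline genes PIWIL2 and TDRD1, which act in the piRNA pathway that silences transposons, were also lower.

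The log2 fold changes were 7.63 for TRIM4 (SE 0.33, adjusted p = 3.35e-04), 2.47 for TRDN (SE 0.18, adjusted p = 0.00282), -7.54 for TSPYL5 (SE 0.67, adjusted p = 0.00683), -5.95 for CGAS (SE 0.49, adjusted p = 0.00415) and -6.85 for MX2 (SE 0.66, adjusted p = 0.00849). PIWIL2 fell from 6.09 ± 0.669 to 0.348 ± 0.0897 CPM (-4.14, SE 0.28, adjusted p = 0.00227). TDRD1 had 3 counts over the CDKO libraries against 206 over CTRL, a ratio of 48.7 (95% interval 16.4 to 238, adjusted p = 0.037). SMIM10 had 2 counts against 662, a ratio of 235 (64.8 to 1940, adjusted p = 0.00735), and the imprinted NAP1L5 had 3 against 547, a ratio of 129 (44 to 629, adjusted p = 0.00415). ZFP3 (-4.72, adjusted p = 9.89e-04), NNAT (-4.65, adjusted p = 0.00415), the metallothionein MT1H (-5.60, adjusted p = 0.037), ZNF311 (-5.20, adjusted p = 0.046), the protease inhibitor SERPINB1 (-4.60, adjusted p = 0.046) and TSPEAR-AS1 (-4.47, adjusted p = 0.0353) fell too. Other large rises were of the scavenger receptor COLEC12 (2.35), MTRNR2L6 (2.01), B4GALNT1 (1.81), PCDHGC4 (1.48), the TGF-beta co-receptor TGFBR3 (1.37), MTRNR2L12 (1.23), EHBP1L1 (1.16) and MPP1 (1.12), with adjusted p from 0.0135 (PCDHGC4) to 0.0439 (COLEC12). Counts are uncertain for TRIM4 (OR2AE1 on its strand), CGAS (DDX43 opposite), NNAT, TSPEAR-AS1 (TSPEAR opposite), PCDHGC4 (exons shared in its cluster), and for MT1H, MTRNR2L6 and MTRNR2L12 with their near-identical copies.

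HOX genes were higher as a group in CDKO iMeLC, with 32 of 32 tested members positive, a median log2 fold change of 1.39, 0 called and 4 called higher adjusted over the list alone (camera adjusted p = 7.71e-11, adjusted p = 0.603 with an estimated correlation). HOXA7 itself stood at 3.20 (adjusted p = 0.0785). As in hESC, HOX genes low in both groups could not enter, which favours genes high in a single group. Mesenchymal transition genes were higher with 15 of 15 positive, 0 called and 6 adjusted over the list alone (camera adjusted p = 2.54e-05, adjusted p = 0.603 with an estimated correlation), with fibronectin FN1 at 0.84 (adjusted p = 0.104). Fibroblast or feeder cell markers were higher with 16 of 16 positive, 0 called and 5 adjusted over the list alone (camera adjusted p = 3.05e-05, adjusted p = 0.603 with an estimated correlation), with the matrix protein gene SPARC at 0.72 (adjusted p = 0.098). Definitive endoderm genes were higher with 0 of 14 called and 5 adjusted over the list alone (camera adjusted p = 3.22e-05, adjusted p = 0.603 with an estimated correlation). Its transcription factors SOX17, GATA6 and GATA4 stood at 1.89, 1.87 and 1.78 (adjusted p = 0.201, 0.293 and 0.169).

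Lists with 0 members called were also higher for dissociation and immediate early genes (16 tested, 5 adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.603 with an estimated correlation) and amnion and trophectoderm genes (19 tested, 0 adjusted over the list alone, 0.00152 and 0.603). The same held for FGF and ERK targets (16 tested, 1 adjusted over the list alone, 0.00238 and 0.669), later mesoderm (16 tested, 1 higher and 1 lower adjusted over the list alone, 0.00238 and 0.603) and NODAL and activin targets (13 tested, 0 adjusted over the list alone, 0.00335 and 0.603). It held as well for mitochondrially encoded genes (13 tested, 3 adjusted over the list alone, 0.0075 and 0.703), WNT targets (16 tested, 0 adjusted over the list alone, 0.0104 and 0.691) and BMP targets (16 tested, 0 adjusted over the list alone, 0.0275 and 0.691). Hypoxia and glycolysis genes were lower, with 0 of 18 called and 1 adjusted over the list alone (camera adjusted p = 0.0275, adjusted p = 0.703 with an estimated correlation), the glucose transporter SLC2A1 standing at -0.56 (adjusted p = 0.0731). Germline and meiosis genes were lower, with 2 of 16 called, PIWIL2 and TDRD1, and the same number adjusted over the list alone (camera adjusted p = 0.0295, adjusted p = 0.603 with an estimated correlation). With upper-quartile factors the germline list had an adjusted p of 0.0654. In other lists, the naive marker KLF5 rose (0.78, adjusted p = 0.0439), as did ETS1 of the neural crest list (0.59, adjusted p = 0.0492). CYTL1 of the primed list fell (-6.44, adjusted p = 0.0375).

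The library CTRL1101 iMeLC stood near the CDKO libraries in several of these lists. Its mean log2 CPM over HOX genes was -0.70, against -2.55 and -2.26 in CTRL1106 and CTRL1109 and -0.57 in CDKO1312. For fibroblast or feeder cell markers it was 4.23 against 4.22 in CDKO1312, for mesenchymal transition 5.33 against 5.42, and for hypoxia and glycolysis 5.53, within the CDKO range of 5.36 to 5.76, where the other CTRL libraries had 6.40 and 6.41. The library CTRL1106 iMeLC stood apart, with lower primitive streak genes and higher SOX2. It held 14.7 CPM of EOMES, 10.4 of TBXT and 20.4 of MIXL1, against 84.6 and 134, 45.8 and 101, and 83.9 and 220 CPM in CTRL1101 and CTRL1109 iMeLC, and 350 CPM of SOX2 against 199 and 130. These genes were picked after their values were seen. Without it the HOX list had an adjusted p of 1.94e-09 (range over single-library omissions 6.26e-13 to 7.66e-08). WNT targets reached 0.25 (range from 5.95e-04), BMP targets 0.274 (range from 0.00374), germline genes 0.233 (range from 0.00138) and hypoxia and glycolysis genes 0.161 (range from 1.39e-05). Hypoxia and glycolysis also reached 0.137 without CTRL1109 iMeLC and 0.103 without CDKO1105 iMeLC. Without CTRL1101 iMeLC germline genes reached 0.0506 and mitochondrially encoded genes 0.36 (range from 4.98e-04). The other 9 lists kept their call in all 6 omissions.

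Of the 69 genes called in iMeLC by edgeR, 69 had no overlap between the groups' libraries, which a call nearly requires, as in hESC. Over all tested genes 26.1% had none, where chance gives 10%. The number of calls depended on single libraries, with 2646 genes without CTRL1101, 32 without CTRL1109, 15 without CDKO1102, 21 without CDKO1105 and 20 without CDKO1312. The balance of directions was not stable, since 76.8% of the 69 genes were lower, against 54.5% with DESeq2 (712 higher and 854 lower), 53.7% in the fit over 12 libraries (606 and 704), 56.8% with no filter (185 and 243) and 44.5% without CTRL1101 (1469 and 1177). Of the 20 genes named for their change, TRIM4 (adjusted p up to 0.008), ZFP3 (0.0155), TRDN (0.0252) and CGAS (0.0499) stayed called in all 6 omissions, as did PIWIL2 (0.0254 at most over its alternatives) and NAP1L5 (0.0484). The other 16 were lost in at least 1 omission, among them TSPYL5 without CDKO1312 (0.0702), MX2 without CDKO1105 (0.0848), and NNAT (0.0538), SMIM10 (0.0619) and SERPINB1 (0.26) without CDKO1102. TDRD1 was lost without CTRL1109 or any 1 CDKO library and reached 0.173 without CDKO1312 (range over alternatives from 8.59e-06). CYTL1 was lost in the same omissions, and KLF5 and ETS1 also without CTRL1106. Without CDKO1102 the adjusted p was 0.214 for CYTL1 (from 2.29e-10), 0.26 for KLF5 (from 1.27e-06) and 0.291 for ETS1 (from 7e-06). Near 0 counts the fitted changes moved by more than 1.5 times on the linear scale, without CDKO1105 to -8.34 for TSPYL5, -6.68 for CGAS and -6.00 for ZNF311. CYTL1 had 0 counts in CDKO without that library and was at least 74.1-fold lower, and its change was -5.86 without CDKO1312. MX2 had 2 counts without CDKO1102, a ratio of 239 (65.8 to 1970), and its change was -6.22 without CDKO1312. The change of MT1H moved to -6.52 without CDKO1102 and -4.99 without CTRL1106, and that of TSPEAR-AS1 to -5.37 without CDKO1312. Without CDKO1105 the count ratios were 87.2 for TDRD1 (15.5 to 3460), 232 for NAP1L5 (41.4 to 9160) and 140 for SMIM10 (38.6 to 1160), and without CDKO1312 SMIM10 had 0 counts in CDKO and was at least 99.9-fold lower.

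Across the 17071 genes tested in both stages, the CDKO against CTRL log2 fold changes of hESC and iMeLC had a Pearson correlation of 0.501 and a Spearman correlation of 0.373. Genes are not independent replicates, and the labels place the same 6 lines behind both stages. There were 22 genes lower in CDKO in both stages where independent lists would share 0.354 (Fisher's exact p = 5.19e-35), and 6 higher in both where they would share 0.0956 (p = 2.99e-10). Both numbers depended on single libraries. Without CDKO hESC 2 only 4 genes were called lower and 1 higher in hESC, and without CDKO1102 only 10 lower and 5 higher in iMeLC, so no more could be shared. The lower genes included TSPYL5, ANKRD35, ZFP3, NNAT, NAP1L5, the interferon-induced genes MX2 and OAS3, the plakophilin PKP3, the laminin chain LAMC3, the calcium channel CACNA1A and the glutamate receptor subunit GRIN1. The higher genes were AC104257.1, B4GALNT1, EHBP1L1, PCDHGC4, TRDN and OLIG2, a neural lineage transcription factor (2.71 in hESC and 5.21 in iMeLC). Without CTRL1109 the iMeLC change of OLIG2 was 6.06. OLIG2 passed in 1 of 6 omissions in each stage, that of CTRL hESC 2 (adjusted p up to 0.139 in the others) and that of CTRL1101 iMeLC (up to 0.221). OAS3 passed in 2 of 6 in each stage (up to 0.107 and 0.155), while PKP3 stayed called in all 6 in iMeLC (up to 0.0155) and in 4 of 6 in hESC (up to 0.0968). LAMC3 passed in 1 of 6 in hESC (up to 0.168) and 2 of 6 in iMeLC (up to 0.133). CACNA1A and GRIN1 each passed in 3 of 6 in hESC (up to 0.18 and 0.146) and 1 of 6 in iMeLC (up to 0.259 and 0.291). No gene was called in opposite directions, but with only 0.299 and 0.113 expected from independent lists this tells little. Of 223 genes called in hESC and tested in iMeLC 190 had the same sign there, and of 66 called in iMeLC 63 had the same sign in hESC. Shared genes can also come from differences between the lines that have nothing to do with the knockout.

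**Figure D1:**
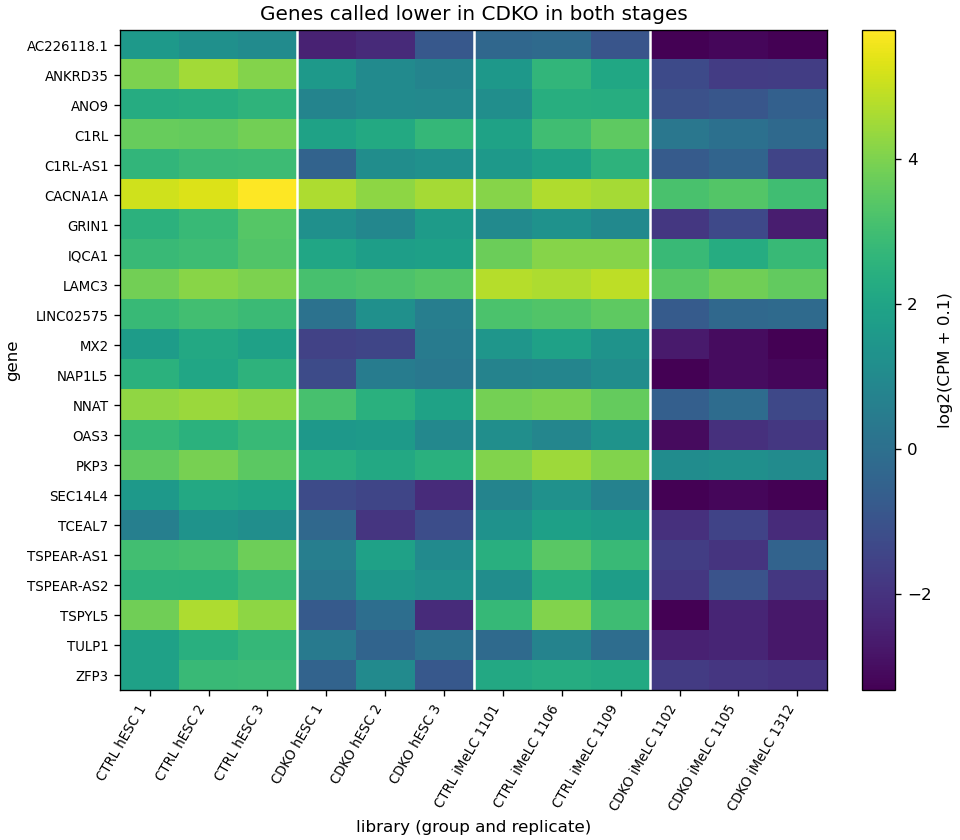
Heat map of log2(CPM + 0.1) for the 22 genes called lower in CDKO in both stages, with genes as lines and the 12 libraries as columns. TSPYL5 averaged 19.3 CPM in CTRL hESC and 0.496 CPM in CDKO hESC.

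**Figure D2:**
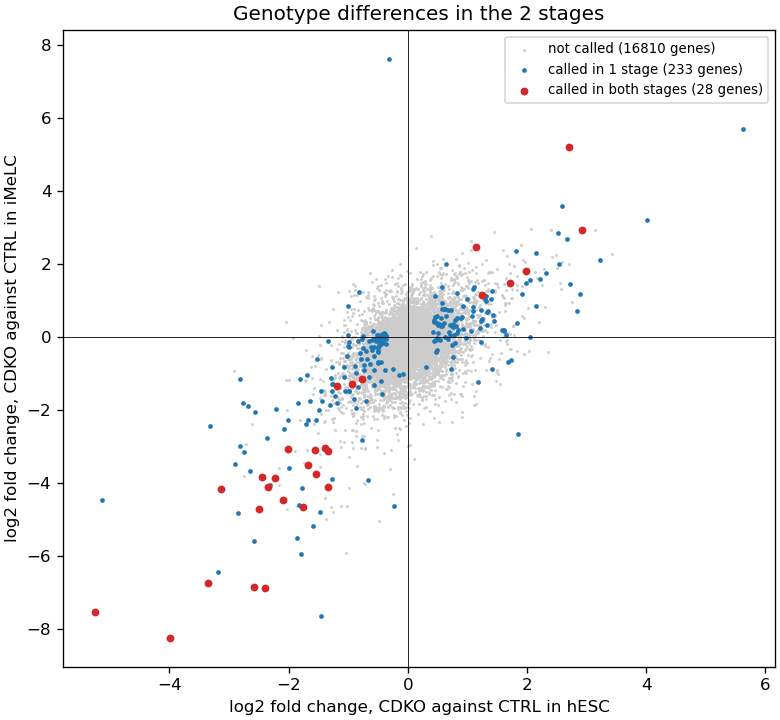
Each point is 1 gene, with the CDKO against CTRL log2 fold change in hESC on the horizontal axis and in iMeLC on the vertical axis, for genes called in 1 stage (233), in both (28) or in neither (16810).

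In CTRL cells, 5981 genes were higher and 4032 lower in iMeLC than in hESC, of 20262 tested. Stage coincided with the table and with depth, so these differences cannot be told apart from differences between the tables. TBXT, the mesoderm transcription factor brachyury, rose from 1.06 ± 1.13 to 58.3 ± 50.3 CPM (SD, n = 3) and the WNT target SP5 from 3.64 ± 3.34 to 190 ± 56.3 CPM. NODAL rose from 25.3 ± 8.39 to 252 ± 101.5 CPM, the mesenchymal cadherin CDH2 from 18.3 ± 3.14 to 210.0 ± 77.2 CPM and the replicative helicase subunit MCM6 from 71.3 ± 6.17 to 280.4 ± 23.9 CPM. The WNT antagonist SFRP1 fell from 428 ± 107 to 28.3 ± 7.23 CPM, and the pluripotency genes L1TD1 and SALL4 also fell.

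The log2 fold changes were 5.83 for TBXT (SE 0.92, adjusted p = 1.54e-04), 5.74 for SP5 (SE 0.63, adjusted p = 6.6e-06) and -3.92 for SFRP1 (adjusted p = 6.37e-07). Other large rises were of NTS, encoding neurotensin (5.63), DKK4 (5.48), the respiratory chain gene COX6C (5.24, SE 0.16, adjusted p = 3.91e-10), GAD1 (5.23), SEC61G of the protein translocon (5.09), GLIPR1L1 (5.09) and TTC29 (4.99). STMN2 had 3 counts over the CTRL hESC libraries and 693 over iMeLC, a ratio of 50.4 (17.2 to 245). Large falls were of TRIM4 (-7.72, adjusted p = 1.9e-09), MTRNR2L7 (-5.75), MAGEA4 (-4.63, adjusted p = 0.00917), SCNN1G (-4.56), HIST2H3PS2 (-4.51), PDE3A (-4.05), POU3F4 (-4.03), HES3 (-3.96) and the adrenergic receptor ADRA2A (-3.95). Counts are uncertain for MTRNR2L7 and HIST2H3PS2, which have near-identical copies, and for TRIM4, MAGEA4, SCNN1G, PDE3A, POU3F4 and GAD1, which overlap other genes. MAGEA4 lost its call without CTRL hESC 2 (adjusted p = 0.17), and the other 19 genes named for their change stayed called in all omissions. DKK4 stood at 2.75, 1.04 and 33.8 CPM in CTRL1101, CTRL1106 and CTRL1109 iMeLC and was counted in CTRL hESC 1 alone among the CTRL hESC libraries (1.11 CPM), and its log2 fold change was 2.72 without CTRL1109 (adjusted p = 0.0401, range over alternatives from 0.00101), 4.88 without CTRL hESC 3 and, with 0 counts left in hESC without CTRL hESC 1, a rise of at least 211-fold. Changes also moved by more than 1.5 times on the linear scale for TBXT (7.18), SP5 (6.81) and GAD1 (5.88) without CTRL hESC 1, and for HIST2H3PS2 (-2.57) and MAGEA4 (-2.37) without CTRL hESC 2. They did so for TTC29 (4.17) and LEF1 (2.34) without CTRL1101, for TBXT (4.90) without CTRL1109, and for SCNN1G (-5.45), POU3F4 (-5.81), HES3 (-4.94) and ADRA2A (-4.88) without CTRL1106. Without that library MAGEA4 had 0 counts in iMeLC and was at least 151-fold lower. The ratio of STMN2 was 96.1 without CTRL hESC 3 (17.2 to 3800).

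The 10 lists that passed camera in CTRL lost the call with an estimated correlation. Mesenchymal transition genes (14 of 15 called higher, 14 adjusted over the list alone, camera adjusted p = 0.00364, adjusted p = 0.637 with an estimated correlation) included FN1 (2.13) and MMP2 (2.81). Fibroblast or feeder cell markers (14 of 15 higher, 14 adjusted over the list alone, 0.00419 and 0.637) included POSTN (3.15) and SPARC (1.38). Cholesterol synthesis genes (14 of 18 higher and 1 lower, the same counts adjusted over the list alone, 0.00419 and 0.628) included FDFT1 (1.44) and NSDHL (1.83). Hypoxia and glycolysis genes (14 of 18 higher and 1 lower, the same adjusted over the list alone, 0.00533 and 0.637) included LDHA (2.27) and ENO1 (1.17). Primitive streak genes (14 of 21 higher, 14 adjusted over the list alone, 0.00642 and 0.637) included FGF8 (4.15) and CDX1 (4.79). Core pluripotency genes were lower (2 of 19 higher and 13 lower, 2 and 14 adjusted over the list alone, 0.00642 and 0.628), with TERF1 at -0.90, L1TD1 at -0.95 and SALL4 at -0.73, while NODAL of that list rose by 3.32. DNA replication genes were higher (11 of 17 higher and 2 lower, the same adjusted over the list alone, 0.0178 and 0.637), with MCM6 (1.98), TYMS (1.79) and PCNA (1.10). HOX genes were higher (13 of 26, 15 adjusted over the list alone, 0.0278 and 0.637), as were WNT targets (10 of 16, 10 adjusted over the list alone, 0.0302 and 0.637), with LEF1 at 3.16. Primed pluripotency genes were lower (1 of 15 higher and 6 lower, the same adjusted over the list alone, 0.043 and 0.628), with SALL2 at -2.04 and CD24 at -1.57. Primed pluripotency reached 0.0693, 0.0833 and 0.101 without CTRL1106, CTRL1101 and CTRL hESC 1 (range over single-library omissions from 0.0252). Without CTRL1101, HOX genes reached 0.128 (from 0.00745), WNT targets 0.135 (from 0.00517) and DNA replication 0.0728 (from 0.00218), and the other 6 lists kept their call in all omissions.

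In CDKO cells, 6510 genes were higher and 5603 lower in iMeLC than in hESC, of 20262 tested. LGALS1, encoding the lectin galectin-1, rose from 1.17 to 129 CPM and COX6C from 3.54 to 172 CPM. Large rises were also of NTS (6.04), AKR1B10 (5.90), TM4SF1 (5.90), the WNT secretion gene WLS (5.43), SEC61G (5.31) and ANXA3 (5.24). Large falls were of the homeobox gene POU3F4 (-5.73), HES3 (-5.38), OLIG3 (-5.38), the serotonin receptors HTR1A (-5.39) and HTR1D (-4.87), CEND1 (-4.93), MIR124-2HG (-5.05), PDE3A (-5.50), CHP2 (-5.47) and HRC (-5.02). The neuroectoderm list did not pass, with 5 of 20 members called higher and 7 lower (camera adjusted p = 0.558). MT1B had 0 counts over the CDKO hESC libraries and was at least 43.3-fold higher in iMeLC (adjusted p = 6.29e-05). MTRNR2L13 had 1 count against 1023, a ratio of 290 (52 to 11500). Both have near-identical copies and are uncertain. All 20 genes stayed called in all omissions. Changes moved by more than 1.5 times on the linear scale for WLS (6.29) without CDKO hESC 3 and for POU3F4 (-6.60) and OLIG3 (-6.03) without CDKO1102. They also did so where few counts were left. Without CDKO hESC 2, AKR1B10 had 1 count in hESC, a ratio of 148 (26.5 to 5850), and TM4SF1 had 3, a ratio of 102 (34.9 to 496). Without CDKO1105, HTR1A had 0 counts in iMeLC and was at least 76.1-fold lower, and MIR124-2HG had 3, a ratio of 89.5 (29.9 to 440). The bound for MT1B was 26.8-fold and 27.6-fold without CDKO hESC 2 and CDKO hESC 3. MTRNR2L13 had a ratio of 180 (32.2 to 7100) without CDKO hESC 2, and with 0 counts in hESC without CDKO hESC 3 it was at least 61.7-fold higher.

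Lists that passed camera in CDKO again lost the call with an estimated correlation. Higher lists were mesenchymal transition (14 of 15, 15 adjusted over the list alone, camera adjusted p = 3.48e-04, adjusted p = 0.662 with an estimated correlation), with FN1 at 2.77, fibroblast or feeder cell markers (14 of 15, 14 adjusted over the list alone, 3.82e-04 and 0.662), with COL3A1 at 5.14, and cholesterol synthesis (14 of 18 higher and 1 lower, 15 and 1 adjusted over the list alone, 0.00275 and 0.662). HOX genes (19 of 26, 21 adjusted over the list alone, 0.00564 and 0.662), WNT targets (13 of 16, 14 adjusted over the list alone, 0.014 and 0.662) and DNA replication (12 of 17 higher and 2 lower, the same adjusted over the list alone, 0.014 and 0.665) were higher too. So were primitive streak genes (14 of 21 higher and 1 lower, the same adjusted over the list alone, 0.0153 and 0.672), hypoxia and glycolysis (11 of 18 higher and 1 lower, the same adjusted over the list alone, 0.0238 and 0.665), mitochondrially encoded genes (10 of 13, 11 adjusted over the list alone, 0.0238 and 0.672) and p53 targets (11 of 18 higher and 2 lower, 12 and 2 adjusted over the list alone, 0.0438 and 0.672), with TP53I3 at 1.23. Core pluripotency was lower (1 of 19 higher and 12 lower, the same adjusted over the list alone, 0.014 and 0.662), with UTF1 at -3.42. The protocadherin beta cluster, of neuronal adhesion genes, was lower (8 of 16, 7 adjusted over the list alone, 0.0197 and 0.662), with PCDHB15 at -1.58, and so were germline and meiosis genes (8 of 18, 7 adjusted over the list alone, 0.0251 and 0.662), with PIWIL2 at -2.10. Without CDKO1312 germline genes and hypoxia and glycolysis reached 0.0686 (from 0.00778 and from 0.0108) and mitochondrially encoded genes 0.0686 (0.072 without CDKO1105, from 0.00955). The p53 targets reached 0.0796 without CDKO1102 and 0.104 without CDKO1312 and stood at 0.05 without CDKO1105 (from 0.0218), and the other 9 lists kept their call in all omissions.

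Another scaling moved the balance of the stage comparisons. With upper-quartile factors the median log2 fold change of all tested genes was -0.386 in CTRL and -0.55 in CDKO, against -0.014 and -0.079 with TMM, and with median-of-ratios factors it was -0.104 and -0.129. Upper-quartile factors called 3903 genes higher and 7539 lower in CTRL (65.9% lower, against 40.3%) and 4113 higher and 9561 lower in CDKO (69.9% lower, against 46.3%). No list with a call in any comparison changed direction under either scaling. With upper-quartile factors the call was lost in CTRL for DNA replication (adjusted p = 0.0627) and primed pluripotency (0.135, and 0.0573 with median-of-ratios factors), and in CDKO for DNA replication (0.0517), mitochondrially encoded genes (0.146), germline genes (0.174) and p53 targets (0.109).

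The interaction, which compares the genotype difference in iMeLC with that in hESC, passed for 4 of 20262 genes, with 3 more positive in iMeLC and 1 more negative, and 2275 genes had an unadjusted p under 0.05. TRIM4 stood at 8.23 CPM in CTRL hESC, 6.64 in CDKO hESC, 0.0364 in CTRL iMeLC and 7.70 in CDKO iMeLC, so it was low in CTRL iMeLC alone (log2 difference 7.94, SE 0.40, adjusted p = 1.24e-06). MTRNR2L12, a humanin-like gene with near-identical copies, stood at 104, 58.7, 40.5 and 97.2 CPM in the same order (2.09, adjusted p = 0.0381). The cholesterol exporter ABCA1 stood at 38.9, 20.6, 12.1 and 33.8 CPM (2.40, adjusted p = 0.0381), and the desmosomal plakophilin PKP3 at 11.3, 4.44, 20.3 and 2.38 CPM (-1.75, adjusted p = 0.0381). FAM120B, next in p, did not pass (-1.09, adjusted p = 0.0507). TET1 stood at -0.12 (adjusted p = 0.78). Upper-quartile factors called 3 genes more positive and 3 more negative (50% lower, against 25%), with a median of all genes of -0.115 against -0.015.

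The lists passing in the interaction had no called member, and each had an adjusted p of 0.809 with an estimated correlation. More positive in iMeLC were fibroblast or feeder cell markers and mesenchymal transition genes (camera adjusted p = 0.0097 for both, 15 tested in each), dissociation and immediate early genes (16 tested, 2 adjusted over the list alone, 0.0117), BMP targets (16 tested, 0.0184) and mitochondrially encoded genes (13 tested, 1 adjusted over the list alone, 0.027). More negative were the protocadherin beta cluster (16 tested, 1 adjusted over the list alone, 0.0117) and germline and meiosis genes (18 tested, 0.0117). None of the 7 lists kept its call in all omissions. The protocadherin list reached 0.11 without CTRL1109 and 0.0588 without CDKO1312 (from 0.0014), and its mean log2 CPM was 1.42 in CTRL1109 against 0.52 and 0.72 in the other CTRL iMeLC libraries and 0.29 to 0.64 in CDKO. Without CTRL1106 the adjusted p was 0.0595 for fibroblast or feeder cell markers (0.0592 without CTRL hESC 1, from 1.9e-05), 0.124 for mesenchymal transition (from 1.53e-04), 0.0876 for dissociation genes (from 0.00553), 0.323 for BMP targets (0.0683 without CTRL hESC 1, from 0.0014) and 0.145 for germline genes (0.0522 without CTRL hESC 1 and 0.059 without CDKO1312, from 3.12e-04). Mitochondrially encoded genes reached 0.721 without CTRL1101, 0.159 without CDKO hESC 1, 0.139 without CDKO1105, 0.087 without CDKO1312 and 0.0683 without CTRL hESC 1 (from 0.00525). TRIM4 stayed called in all 12 omissions (adjusted p up to 1.7e-05). MTRNR2L12 passed in 3 of 12, without CDKO hESC 1, CDKO hESC 2 or CTRL1101 iMeLC, ABCA1 in 3, without CTRL hESC 2, CTRL1101 iMeLC or CDKO1105 iMeLC, and PKP3 in 2, without CTRL hESC 2 or CTRL1101 iMeLC. Their adjusted p rose to 0.142 without CDKO1102 iMeLC, 0.185 without CDKO hESC 2 and 0.162 without CTRL hESC 1. The count was 439 without CTRL1101 iMeLC and 1 to 4 without any other library.

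**Figure D3:**
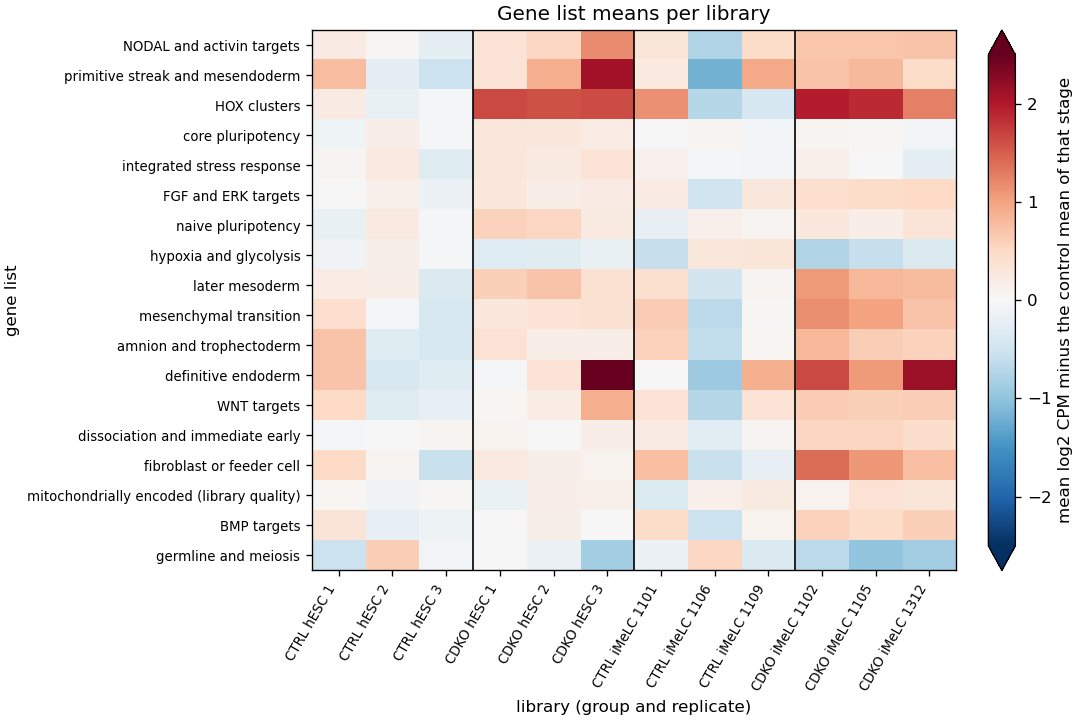
Colours give, for 18 gene lists and the 12 libraries, the mean log2 CPM of a list minus its mean over the CTRL libraries of the same stage, with the scale clipped at 2.5 in both directions. CTRL libraries spread around 0 because they are their own reference, and HOX genes had a median log2 fold change of 1.39 in CDKO iMeLC.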

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

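No test in this part was chosen after its result was seen. The genotype difference in iMeLC differed from that in hESC, by the test of the interaction itself, for 4 genes. TRIM4 had a log2 difference of 7.94, MTRNR2L12 of 2.09, ABCA1 of 2.4 and PKP3 of -1.75. By the same test 7 gene lists passed camera with a preset correlation, none passed with an estimated correlation (0) and none passed fry (0). Of 100 drawn splits of genotype within the stages, the real one included, 6 called at least 4 genes, the number called with the real labels. The other 5 all kept the real iMeLC grouping, as labelled or with the labels swapped. They carry the iMeLC genotype difference and so are no measure of chance. The share therefore decides nothing, and chance is not excluded for that number. The split with the most calls, 1222 genes, swapped the genotype labels in iMeLC alone, so that its interaction sums the genotype effect over the stages. It points to a structure of the samples, a difference between the genotype groups common to both stages, which differences between the lines unrelated to the knockout would give as well.

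The other comparisons allow only 10 splits of 3 libraries against 3, too few for a share under 0.05, and in each of them 1 split, the real one, reached the real value. In hESC the real split called 226 genes and the highest other 3. In iMeLC it called 69 and the highest other 0, by edgeR. For iMeLC against hESC it called 10013 in CTRL, with 2 as the highest other, and 12113 in CDKO, with 0 as the highest other. The correlation of genotype effects between the stages, 0.501, was reached by 1 of 100 pairs of splits, the real one, with 0.388 as the highest other, but the lines behind both stages allow only 10 splits, again too few.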

How the results depend on the processing

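Of the alternatives reported in this part, leaving out single libraries in the fits over both stages, for the correlation of genotype effects and in the list tests, removing AL627171.2 and rescaling the list tests were chosen after the results were seen. No paired analysis was possible because the hESC columns carry no line number, and for the same reason the planned line block and the omission of both libraries of a line were not run. Of 2856 values of named genes under an alternative, 2437 kept their direction and their side of the threshold, 323 lost the call, 41 gained one and 55 changed sign, none of these in a called gene. The deeper iMeLC libraries did not give more power, since 41.5% of simulated 2-fold changes were recovered there and 70.3% in hESC, with a biological coefficient of variation of 0.275 against 0.137. Depth limited the lowest levels, as thinning the iMeLC counts to the hESC totals put 5 instead of 3 of the 22 genes lower in both stages at the floor.

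The 226 genes called in hESC became 618 with DESeq2 (225 shared), 1228 with no filter on low counts (226 shared), 72 in the fit over 12 libraries (66 shared) and 5 to 493 when single libraries were left out. The 69 in iMeLC became 1566 with DESeq2, 428 with no filter and 1310 in the fit over 12 libraries (69 shared in each), 27 with limma-voom (27 shared) and 15 to 2646 over single omissions. The 4 of the interaction became 217 with DESeq2 and 29 with no filter (4 shared in each), 1 with limma-voom and 1 to 439 over single omissions. Stage calls ranged over single omissions from 8527 to 9925 in CTRL and from 10817 to 11201 in CDKO. Without mitochondrially encoded and small RNA genes 226, 65 and 5 genes passed in hESC, in iMeLC and for the interaction, and 226, 64 and 5 without AL627171.2 as well. The TET1 log2 fold change lay between 0.20 and 0.32 in hESC and between 0.042 and 0.15 in iMeLC when single libraries were left out. The correlation of genotype effects, 0.501, was 0.407 to 0.516 over omissions, 0.569 with at least 1 CPM in 3 libraries and 0.52 with a mean log2 CPM of at least 4.

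The 9 lists called in hESC, 14 in iMeLC, 10 and 13 for the stages in CTRL and CDKO and 7 for the interaction became 0 in each comparison when camera estimated the correlation, and 1, 0, 22, 26 and 0 with fry. With upper-quartile factors 11 passed for the interaction. Over single omissions 7 to 15 passed in hESC, 11 to 15 in iMeLC, 8 to 11 and 9 to 15 for the stages in CTRL and CDKO and 3 to 14 for the interaction.

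Changes of sign were seen in genes that were not called. Given as the lowest and highest log2 value over single omissions, they were in hESC KDR (-0.099 to 0.062), and for the stage difference in CTRL TET1 (-0.15 to 0.032). In iMeLC they were CCND1 (-0.060 to 0.66), SP5 (-0.39 to 0.028), SMAD7 (-0.0077 to 0.63), ID1 (-0.21 to 0.047), ID3 (-0.0049 to 0.54), PHLDA1 (-0.28 to 0.097), IER2 (-0.055 to 0.33), MT-CO1 (-0.19 to 0.13), MT-ND4 (-0.11 to 0.25), MT-CO2 (-0.027 to 0.31) and MT-ND5 (-0.12 to 0.26). For the interaction they were TET2 (-0.018 to 0.38), TET3 (-0.11 to 0.061), RBM46 (-5.19 to 1.91), MEIOC (-0.53 to 0.35), SMAD7 (-0.45 to 0.19), VIM (-0.014 to 1.10), CDH2 (-0.15 to 0.52), COL1A2 (-0.16 to 0.50), IER2 (-0.12 to 0.26), MT-CO1 (-0.24 to 0.067), MT-ND4 (-0.075 to 0.28), MT-CO2 (-0.036 to 0.29) and MT-ND5 (-0.086 to 0.28). MT-CO1 also changed sign with median-of-ratios factors (0.0060 in iMeLC and 0.0097 for the interaction) and with DESeq2 (0.0060 and 0.0097). The cause was not tested for any change in this part, beyond the fewer libraries of an omission.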

Other observations

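The length test, the X chromosome test and both tests of CpG content in this part were chosen after the result was seen, and so were the gene groups of the next paragraph.

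Interferon-induced genes, which encode antiviral proteins, held 2 genes lower in CDKO in both stages. MX2 stood at -2.58 in hESC (-3.79 without CDKO hESC 3) and -6.85 in iMeLC, and OAS3, an oligoadenylate synthetase, at -1.34 and -4.13 on the log2 scale. Of 18 interferon-induced genes tested in hESC and 20 in iMeLC these were the ones called lower, while 1, IFIT3, was called higher in hESC. The group was formed after the calls were seen, so a test of its share among the called genes would restate that choice and is not given. When single libraries were left out, MX2 passed in 3 of 6 omissions in hESC (lost without CTRL hESC 1, CDKO hESC 1 or CDKO hESC 2, adjusted p up to 0.184) and 5 of 6 in iMeLC (0.0848 without CDKO1105), and OAS3 in 2 of 6 in each stage (up to 0.107 without CDKO hESC 2 and 0.155 without CDKO1105). Zinc finger genes had 2 called lower in each stage, of 488 and 504 tested, and 2 called higher in hESC, ZNF486 and ZNF878. They made up 1.63% of the genes called lower in hESC and 3.77% in iMeLC, near their 2.83% and 2.52% of all tested genes. Of 9 metallothioneins tested in iMeLC, MT1H was called lower. SOX17 and GATA6, endoderm transcription factors chosen after their values were seen, did not overlap between the iMeLC groups. The same held for 26.1% of all genes tested in iMeLC, where chance gives 10%. SOX17 stood at 8.07, 2.6 and 22.3 CPM in the CTRL libraries and 35.9, 25.2 and 61.4 CPM in CDKO, and GATA6 at 12.6, 1.8 and 44.1 against 63.3, 45.1 and 106 CPM, and neither passed the test (edgeR adjusted p = 0.201 and 0.293).

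With all libraries kept, 22 genes were lower in CDKO in both stages. Without CDKO hESC 2 only 4 genes were called lower in hESC, so at most 4 of the 22 could stay called in both. The state of the X chromosome is argued against as the common cause of the 22, since 4.55% of them (1 of 22, exact interval 0.115 to 22.8) were X-linked. Copy number differences between the lines that reach neighbouring genes are undecided as the common cause of the 22 by the rule set beforehand. The 20 nearest genes of each had a median log2 fold change of -0.07 in iMeLC (-0.11 to -0.02). The level set beforehand for such a change was -0.3, outside that interval, and 2 of 22 had neighbours below it. The lower end of the interval just missed the level set beforehand for setting this cause aside. A change confined to a gene itself, or one behind those 2 genes, stays open too. Differences between the lines unrelated to the knockout may also be the source. Of 100 pairs of splits 1, the real one, shared as many genes (highest other 0), but the lines allow only 10 splits. Other splits called at most 3 genes in hESC and 0 in iMeLC. No other pair could therefore share as many, and the comparison decides nothing. An effect of the knockout itself stays open beside such differences.

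These 22 genes fell less in hESC (median log2 fold change -2.05) than in iMeLC (-4, or -3.97 with the 3 genes of 3 or fewer counts at the floor), and the interaction passed for 1 of them. Background reads are argued against for the middle of the 22, as 376 olfactory receptor genes reached 3.15% (1.55 to 5.08) of their level per kilobase in CDKO hESC, by medians. Summed over those receptor genes, background was higher in CDKO hESC (17.3, 21 and 25.4 CPM) than in CDKO iMeLC (4.66, 4.11 and 4.17 CPM). The ratio of medians does not cover members near the floor in CDKO hESC, such as SEC14L4 (0.33, 0.28 and 0.12 CPM). Depth is argued against, as thinning the iMeLC counts to the hESC totals left a median of -3.83 (-4.89 to -3.09), or -3.84 with 5 genes at the floor. The choice of genes by the more variable iMeLC test stays open, as all 22 fell more in iMeLC, while the 47.1% (38 to 56.4) among 121 genes called lower in hESC and tested in iMeLC decides nothing, since being called in hESC enlarges the hESC falls and lowers that share. No biological explanation was tested.

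COX6C and SEC61G rose by 5.24 and 5.09 on the log2 scale from hESC to iMeLC in CTRL and by 5.59 and 5.31 in CDKO, although both are used by nearly all cells. A bias by gene length stays open. The 4986 genes of similar exon length had a median of -0.08 (-0.11 to -0.05). Those lengths, 3066 for COX6C and 1842 for SEC61G, merged the exons of all annotated transcripts of a gene. They can exceed the length of the mRNA that was sequenced, so the test does not speak for short mRNAs. Reads shared with processed pseudogenes and counted differently in the tables could contribute and stay open, since 433 genes with such copies stood 0.38 (0.26 to 0.51) above matched genes without. COX6C has 17 such pseudogenes and SEC61G 0. A biological difference between the stages cannot be told apart from a difference between the tables.

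A hypothesis was that genes lower in CDKO have CpG-rich 5' ends, as they might if promoter methylation had risen. The median ratio of observed to expected CpG was 0.646 in the genes lower in iMeLC and 0.681 in expression-matched draws, a difference of -0.036 (permutation p = 0.5, 52 of 53 genes). In hESC it was 0.673 against 0.747, a difference of -0.074 in the opposite direction to the hypothesis (permutation p = 0.02, 122 of 123 genes). Neither result goes with the hypothesis. The ratio was taken over the first 300 nt of 1 annotated spliced transcript per gene. Sequence upstream of the start was not examined and methylation was not measured, so the results do not speak for the promoters themselves.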
